A study of Mus musculus with 12 samples.

How the data were processed

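The log2 values were used as deposited by the authors, who made them, per the submitters' processing notes, in Affymetrix Expression Console with RMA, a method that corrects background, normalizes by quantiles and summarizes probes. No further normalization was applied for the reported results. The table held 34760 probe sets, and the platform annotation listed 22961 of them, of which 21640 named 1 gene and 1321 named several genes, while 11799 probe sets were not listed. Probe sets that named 1 gene were kept and each gene took its brightest probe set by mean over all arrays, which gave 19937 genes, 954 of them with several probe sets. Entrez identifiers of 21553 probe sets were matched to a GRCm38.p6 gene table, used for names alone, and 0 symbols changed. The genome build of the annotation was not needed for any result.

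A linear model with 1 mean per group was fitted to all 12 arrays in limma (residual df 8, prior df 4.83), with empirical Bayes moderation and 7 contrasts: smoke against air in each genotype, genotype in each exposure, their interaction and both averages. Tests were 2-sided, and p-values were adjusted by Benjamini-Hochberg over all genes of a contrast, with a limit of 0.05. The standard error of a difference was the moderated one. Gene lists, 42 in number and fixed from general knowledge (834 of 897 members measured), were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a contrast. They were tested again with the correlation estimated from the data and with fry. Counts given as adjusted over the list alone took the limma p-values of the members and adjusted them within the list. Medians of members describe size and carry no test of their own.

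Named genes followed a rule: per comparison the largest rises and falls among genes past the test whose groups did not overlap, up to 4 members of each called list with the smallest p, and a fixed set that included Rela, Ctnnb1, Ccnd1, Axin2, Myc, Mki67 and genes of inflammation, smoke response and lung epithelium. The groups, contrasts, lists, thresholds, naming rule and alternatives were chosen before the data were examined. The alternatives were an intensity filter (log2 of at least 6 in at least 3 arrays, 15007 genes), the mean of a gene's probe sets, every probe set by itself, an intensity trend in the prior, array weights, quantile normalization, centring of each array on its median, the replicate number as a block, fitting the 6 arrays of a comparison alone, and leaving out each array in turn. Group labels were also exchanged between arrays to count calls by chance. The method was tested on simulated data in which 200 genes were shifted by 0.5 or 1 log2 unit and the other members of 1 gene list by 0.4. It called 100 of 100 genes shifted by 1, 67 of 100 shifted by 0.5, the shifted list and 8 of the 19704 genes left unshifted, and with no gene shifted in the second smoke comparison it called 0 genes. The simulated genes were drawn independently of each other. The simulation therefore does not show how often lists are called wrongly when genes are correlated. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used. Probe sets without a gene or with several genes were left out, and raw array images were not reprocessed.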

Results

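RNA of Lewis lung carcinoma tissue, taken out of the lungs of female C57BL/6 mice, was measured on 12 Affymetrix mouse gene arrays. Lewis lung carcinoma is a transplantable mouse tumour line, so the tissue can hold tumour cells and cells of the host lung. Hosts were wild type or deficient in RelA/p65, a subunit of the transcription factor NF-kB, and had been exposed to air or to smoke, which gave 4 groups of 3 arrays. Median log2 expression per array lay between 6.78 and 6.88, and arrays of 1 group correlated with r from 0.990 to 0.998 across genes. The first principal component held 79.7% of the variance and ordered the groups as wild type smoke (mean score -64.1), wild type air (-12.0), deficient smoke (35.4) and deficient air (40.8). Gene levels below are log2 expression, as group mean ± SD (n = 3 arrays), and changes are log2 differences ± SE from limma with an adjusted p. The number of arrays limits the precision of every value. The labels do not say that the replicates of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

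Rela, the gene that encodes RelA/p65, was not lower in the arrays labelled RelA/p65 deficient. Its level was 9.22 ± 0.06 in wild type air, 9.08 ± 0.10 in wild type smoke, 9.42 ± 0.04 in deficient air and 9.31 ± 0.05 in deficient smoke, from the 1 probe set that names the gene. Averaged over exposures it was higher in the deficient arrays by 0.22 ± 0.05 (adjusted p = 0.0013). The difference was 0.20 in air (adjusted p = 0.0285) and 0.23 in smoke (adjusted p = 0.00873). With each array centred on its median, these were 0.12 (adjusted p = 0.142) and 0.09 (adjusted p = 0.213). The air difference also missed the test without wild type air replicate 2, deficient air replicate 1 or deficient air replicate 2, with a difference of 0.17 to 0.19. The labels do not state which part of the gene was deleted, the series title speaks of myeloid cells, and RNA of tumour and host cells that kept the gene is part of the tissue. The groups are therefore called arrays labelled RelA/p65 deficient, or deficient arrays for short.

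Smoke exposure in wild type hosts was compared first, to ask what differed with smoke in the tumour tissue. The largest fall was that of Cyp2f2: this cytochrome P450 of airway club cells fell by 5.35 ± 0.08 (40.8-fold; adjusted p = 2.15e-13), and Scgb1a1, the club cell secretory protein, fell by 4.46 ± 0.11. The carboxylesterase Ces1d, the flavin monooxygenase Fmo2, the retinal dehydrogenase Aldh1a1 and the endothelial gene Tmem100 fell by 4.53, 4.36, 4.21 and 4.30. Among the largest rises, the neutrophil chemokine Cxcl2 rose by 2.04 ± 0.21 (4.10-fold; adjusted p = 6.50e-06), the macrophage protein Cd5l by 2.03 ± 0.23, the chemokine Ccl3 by 1.87 ± 0.24, placental growth factor Pgf by 1.61 ± 0.14 and arginase Arg1 by 1.5 ± 0.18.

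All 23 alveolar epithelial markers fell, over all genes and adjusted over the list alone, with a median of -1.96 (list adjusted p = 1.40e-35). The type I cell gene Ager fell by 2.95 ± 0.07 and the surfactant protein genes Sftpa1 and Sftpc by 2.49 ± 0.07 and 1.58 ± 0.06. Of 23 airway epithelial markers 16 fell and none rose (also 16 adjusted over the list alone), with a median of -1.16. Endothelial markers moved the same way, with 20 of 23 lower (21 adjusted over the list alone), a median of -0.82 and falls of 2.62 ± 0.07 for the receptor kinase Tek and 1.93 ± 0.08 for the VEGF receptor Kdr. Epithelial junction and keratin genes had 12 of 19 lower and 1 higher (12 and 2 adjusted over the list alone), among them E-cadherin, Cdh1, at -2.59 ± 0.08. The adjusted p with an estimated correlation was 0.0848 for the alveolar list, 0.0848 for the airway list, 0.105 for the endothelial list and 0.131 for the junction list. Smooth muscle markers (8 of 13 lower, 1 higher, the same adjusted over the list alone) and cardiac and skeletal muscle markers (11 of 19 lower, 3 higher; 11 and 4 adjusted over the list alone) shifted by a median of -0.44 and -0.34, the latter -0.58 with the intensity filter. Both were called, with an adjusted p of 0.269 with an estimated correlation. The cardiac genes Myl7 and Actc1 fell by 3.30 ± 0.09 and 2.67 ± 0.09. Fibroblast and matrix genes went both ways, 10 higher and 15 lower of 27 (11 and 15 adjusted over the list alone), with a median of -0.27 (-0.18 with median centring), and their adjusted p was 0.136 with an estimated correlation. The lung fibroblast genes Npnt, Inmt and Tcf21 fell by 3.48, 3.95 and 2.40.

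Macrophage and monocyte markers rose beside this fall of lung markers, with 20 of 25 higher and 2 lower (the same adjusted over the list alone) and a median of 0.86 (adjusted p = 1.06e-07; adjusted p = 0.269 with an estimated correlation). The mannose receptor Mrc1 rose by 1.11 ± 0.10, the complement gene C1qc by 1.11 ± 0.10 and the growth factor receptor Csf1r by 0.65 ± 0.06, while the lysozyme gene Lyz1, also made by alveolar type II cells, fell by 1.96 ± 0.09. Wild type air replicate 1 stood apart here, with a mean of 8.99 for this list against 8.65 and 8.66 in the other wild type air arrays. Alveolar macrophage and smoke-macrophage markers went the other way, 3 higher and 9 lower of 16 (the same adjusted over the list alone), with a median of -0.37 and an adjusted p of 0.107 with an estimated correlation. The carbonic anhydrase Car4 fell by 3.84 ± 0.11 and the chitinase-like gene Chil3 by 1.99 ± 0.14. Of 32 chemokines 18 rose and 4 fell (the same adjusted over the list alone), with a median of 0.47. Ccl8 rose by 1.46 ± 0.13 and the lung chemokine Cxcl15 fell by 2.74 ± 0.11. The chemokine call had an adjusted p of 0.421 with an estimated correlation and missed the test with median centring (adjusted p = 0.0577).

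Among 36 NF-kB target genes 20 rose and 3 fell (22 and 3 adjusted over the list alone), with a median of 0.24 (adjusted p = 0.00348; adjusted p = 0.474 with an estimated correlation). Cxcl1 rose by 0.79 ± 0.10, Il1b by 1.24 ± 0.24 and Tnf by 0.39 ± 0.08, the adhesion molecule Icam1 fell by 1.88 ± 0.08, and Il6, at 3.75 ± 0.07 in wild type smoke, did not pass. Immune checkpoint and suppression genes had 7 of 14 higher (8 adjusted over the list alone) with a median of 0.27, among them the nitric oxide synthase Nos2 at 0.98 ± 0.15. Neutrophil markers had 12 of 24 higher and 3 lower (14 and 3 adjusted over the list alone) with a median of 0.29 (0.52 with the intensity filter), among them S100a8 at 0.67 ± 0.08, while Chil1 fell by 2.57 ± 0.08. The adjusted p with an estimated correlation was 0.269 and 0.131, and the neutrophil call missed the test with median centring (adjusted p = 0.051). Alveolar epithelial markers lay 1.96 lower in the same comparison.

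Of 33 mitotic genes 15 passed the test, all higher (24 adjusted over the list alone), with a median of 0.38 (adjusted p = 5.24e-05; adjusted p = 0.573 with an estimated correlation). Cdc20, the activator of the anaphase complex, rose by 0.50 ± 0.10 and the kinetochore gene Ndc80 by 0.41 ± 0.10, while Mki67 was 0.38 ± 0.14 higher without passing (adjusted p = 0.0575). Of 31 DNA replication genes 11 rose (15 adjusted over the list alone), with a median of 0.28 and an adjusted p of 0.573 with an estimated correlation. Hypoxia and glycolysis genes had 18 of 26 higher and 2 lower (19 and 2 adjusted over the list alone) with a median of 0.45 (adjusted p = 3.60e-05; adjusted p = 0.358 with an estimated correlation). Adrenomedullin, Adm, rose by 1.25 ± 0.13 and the oxidoreductase Ero1a by 0.89 ± 0.09, while Vegfa, also made by alveolar type I cells, fell by 1.27 ± 0.07. Myc rose by 0.89 ± 0.14 (adjusted p = 3.03e-04), and Ccnd1 at 0.01 ± 0.09 did not pass. Endothelial and alveolar markers fell in the same arrays, by medians of -0.82 and -1.96.

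B cell markers (7 of 17 lower, the same adjusted over the list alone; median -0.32) and p53 targets (7 of 17 lower and 1 higher; 9 and 1 adjusted over the list alone; median -0.18) were called lower, with adjusted p of 0.307 and 0.281 with an estimated correlation. The B cell median was -0.17 with array weights and -0.20 without wild type smoke replicate 1, and that of p53 targets -0.0912 with median centring. Ms4a1, which encodes CD20, fell by 1.90 ± 0.09. MHC class II genes had 4 of 10 lower and 1 higher (the same adjusted over the list alone) with a median of -0.27, and Cd74, the invariant chain, fell by 0.90 ± 0.11. That call had an adjusted p of 0.559 with an estimated correlation and was lost with the intensity filter (adjusted p = 0.111) and without wild type air replicate 1 (median -0.14, adjusted p = 0.118). Interferon response genes were not called (median 0.14, 2 of 26 lower, none higher, the same adjusted over the list alone). Their mean was 8.18 in wild type air replicate 1 against 7.38 and 7.39 in the other wild type air arrays, and without that array the list was called higher, with a median of 0.38 (adjusted p = 0.0047). Wnt/beta-catenin targets had 6 higher and 7 lower of 27 (7 and 8 adjusted over the list alone) and were not called.

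Over all 19937 genes 5778 changed, 2991 higher and 2787 lower, of which 68 rose and 645 fell at least 2-fold. The groups did not overlap for 36.9% of genes, against 10% by chance. With median centring 77.1% of the changed genes were higher in place of 51.8%, and their number was 9852. That centring moved the median change of all genes from 0.08 to 0.17, away from 0. Without wild type air replicate 3 the count was 3695 and without wild type smoke replicate 1 it was 8824. Of 42 gene lists 19 were called, 8 higher and 11 lower, and none held with an estimated correlation, while fry, which tests each list without comparing it with other genes, called 29.

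**Figure D1:**
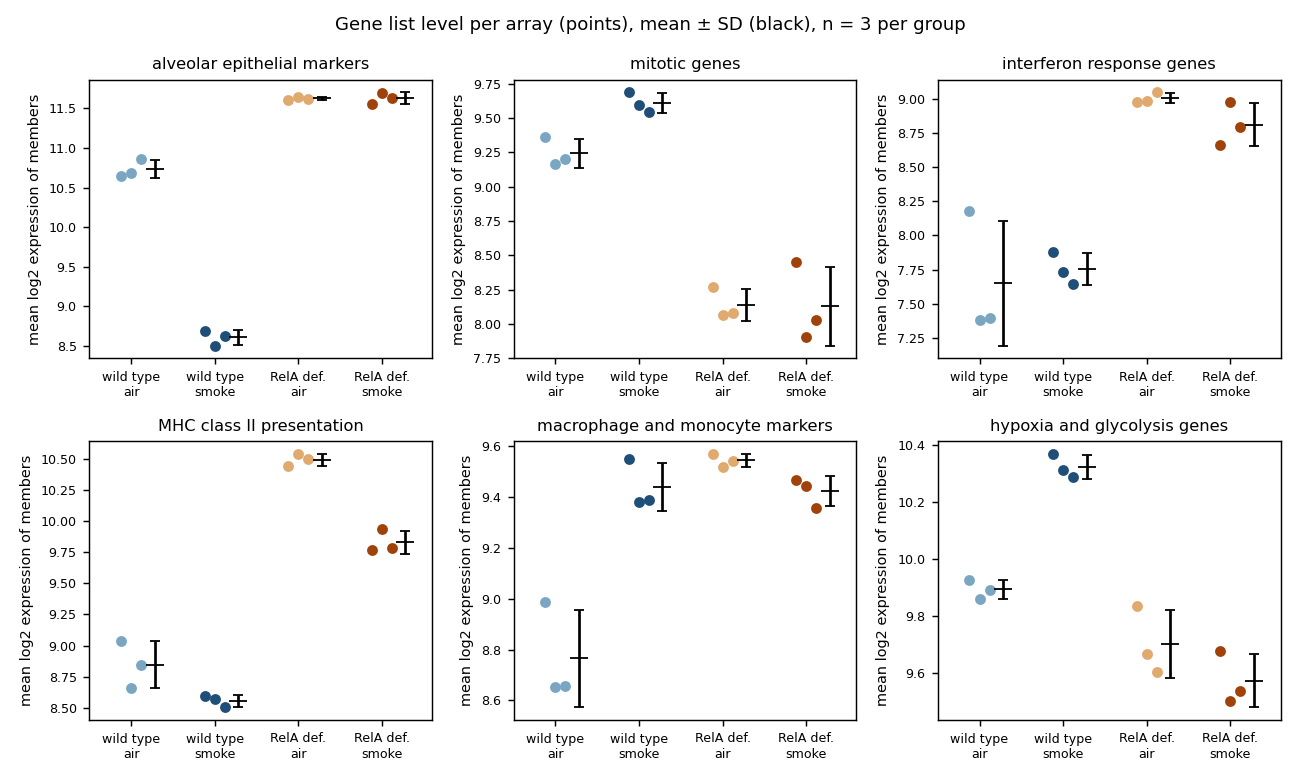
Mean log2 expression of the members of 6 gene lists (vertical axis) on each array (points) in the 4 groups (horizontal axis), with the group mean and SD in black (n = 3). Alveolar markers lay at 8.61 ± 0.10 in wild type smoke and 11.6 ± 0.02 in deficient air, and mitotic genes at 9.61 ± 0.07 and 8.14 ± 0.11.

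Smoke exposure was next compared within the deficient arrays. Cyp1a1, the cytochrome P450 induced through the aryl hydrocarbon receptor, rose by 5.08 ± 0.10 (33.7-fold; adjusted p = 6.60e-12), from 6.47 ± 0.14 to 11.5 ± 0.09. A second enzyme of that family, Cyp1b1, rose by 2.35 ± 0.10 (5.12-fold), the quinone reductase Nqo1 by 1.5 ± 0.10 and the aldehyde dehydrogenase Aldh3a1 by 1.5 ± 0.13. The MHC class II chain gene H2-Ea rose by 2.38 ± 0.32, the haem synthesis gene Alas2 by 1.34 ± 0.09 and the resistin-like gene Retnla by 1.17 ± 0.11. The immunoglobulin gene Igkv19-93 fell by 3.05 ± 0.11 (8.26-fold), and by 1.56 as the mean of its probe sets. The tripartite motif gene Trim12a fell by 2.73 ± 0.10, the myeloid receptor genes Adgre4 and Treml4 by 2.40 ± 0.10 and 2.16 ± 0.14, Jchain, the antibody joining chain, by 2.24 ± 0.16, and the tryptophan-degrading enzyme Ido1 by 1.96 ± 0.16.

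Of 9 aryl hydrocarbon receptor targets 4 rose and none fell (the same adjusted over the list alone), and the list call held with an estimated correlation (adjusted p = 8.57e-09 and 0.0183). The median of this short list was 0.05, but 1.5 with the intensity filter, which leaves out its dim members. It was 0.0835 with array weights, 0.0243 with quantile normalization, and 0.13, 0.10 and 0.0238 without deficient smoke replicate 1, 2 or 3, and the list was called in each of these settings. NRF2 antioxidant genes had 4 of 22 higher (9 adjusted over the list alone) with a median of 0.15, and an adjusted p of 0.0812 with an estimated correlation. The glutathione synthesis gene Gclc rose by 0.59 ± 0.06, the carbonyl reductase Cbr3 by 0.58 ± 0.08 and the glutathione peroxidase Gpx2 by 0.69 ± 0.09. Alveolar epithelial markers were not called beside them (median -0.00, 1 of 23 higher, the same adjusted over the list alone).

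MHC class II genes had 4 of 10 lower (9 adjusted over the list alone) and a median of -0.50 (adjusted p = 2.96e-15; adjusted p = 0.0389 with an estimated correlation). Ciita, their master regulator, fell by 1.04 ± 0.08 and the chain gene H2-Ob by 1.36 ± 0.11. MHC class I presentation genes had 6 of 12 lower (9 adjusted over the list alone) with a median of -0.33, among them the peptide transporters Tap1 and Tap2 at -0.79 ± 0.13 and -0.56 ± 0.07. T and NK cell markers had 8 of 30 lower (14 adjusted over the list alone) with a median of -0.21, and granzyme A, Gzma, fell by 1.02 ± 0.11. B and plasma cell markers had 5 of 17 lower (9 adjusted over the list alone) with a median of -0.37, and Ms4a1 fell by 0.90 ± 0.09. The adjusted p with an estimated correlation was 0.0792, 0.0716 and 0.054 for these 3 lists. Dendritic cell markers had 4 of 14 lower (5 adjusted over the list alone), with the cross-presenting cell genes Xcr1 and Clec9a at -0.69 ± 0.10 and -0.67 ± 0.11, and an adjusted p of 0.099 with an estimated correlation. Cd274, which encodes PD-L1, fell by 1.34 ± 0.12.

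Neutrophil markers had 5 of 24 higher (5 adjusted over the list alone) with a median of 0.13 (0.0772 without deficient air replicate 3), among them S100a8 and S100a9 at 0.57 ± 0.08 and 0.59 ± 0.10. Alveolar macrophage and smoke-macrophage markers had 4 of 16 higher (7 higher and 1 lower adjusted over the list alone) with a median of 0.20, among them the transporter Slc7a2 at 0.47 ± 0.06 and Gpnmb at 0.78 ± 0.13. Erythroid and platelet markers had 2 of 8 higher (3 adjusted over the list alone), Alas2 and the red cell anion exchanger Slc4a1 (1.07 ± 0.10), with a median of 0.15 (0.24 with the intensity filter). These 3 calls held with an estimated correlation, each at an adjusted p of 0.0389. Macrophage and monocyte markers were not called (median -0.03, 4 of 25 lower; 6 lower and 1 higher adjusted over the list alone). They were called lower in 6 of 19 settings, with a median of -0.10 (adjusted p = 0.0231) without deficient smoke replicate 1. The others were median centring (adjusted p = 0.0272), the replicate number as a block (0.0393), and leaving out wild type air replicate 1 (0.00773), deficient air replicate 1 (0.0437) or deficient smoke replicate 2 (0.0241).

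Mitotic genes did not pass as a list (median 0.01, none of 33 past the test, none adjusted over the list alone). Their mean was 8.45 in deficient smoke replicate 1 against 7.90 and 8.03 in the other deficient smoke arrays, and without that array the list was called lower, with a median of -0.17 (adjusted p = 4.96e-08). Without deficient smoke replicate 2 it was called higher, with a median of 0.11 (adjusted p = 0.00276). NF-kB targets were called lower with a median of -0.07 (5 of 36 lower; 6 lower and 1 higher adjusted over the list alone), and an adjusted p of 0.386 with an estimated correlation. Cd83, an activation marker of antigen-presenting cells, fell by 0.53 ± 0.08. Tnf fell by 0.44 ± 0.08, a call lost without deficient air replicate 1 or 2 (adjusted p = 0.0521 and 0.0563). No member of the Wnt/beta-catenin target list passed.

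In all 481 genes changed, 138 higher and 343 lower, of which 11 rose and 43 fell at least 2-fold, and 22.7% of genes did not overlap between the groups (10% by chance). Leaving out any 1 of the 6 arrays compared gave 261 to 320 genes, and fitting these 6 arrays alone gave 1018. Of the lists 25 were called, 10 higher and 15 lower. The aryl hydrocarbon receptor, MHC class II, erythroid, alveolar and smoke-macrophage, and neutrophil calls were the 5 that held with an estimated correlation.

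**Figure D2:**
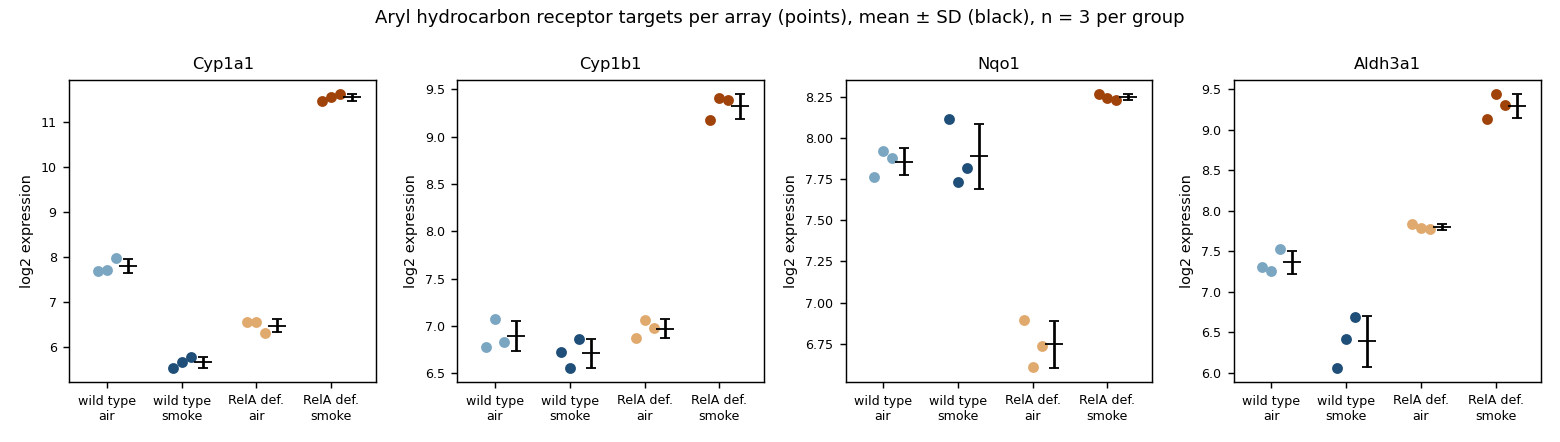
Log2 expression (vertical axes) of 4 aryl hydrocarbon receptor targets on each array (points) in the 4 groups, with mean and SD in black (n = 3). Cyp1a1 lay at 7.79 ± 0.16 in wild type air, 5.65 ± 0.13 in wild type smoke, 6.47 ± 0.14 in deficient air and 11.5 ± 0.09 in deficient smoke.

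Host genotype was compared in air to ask how tumour tissue of deficient hosts differed without smoke. The largest rises included interferon-inducible genes: Ly6i was higher in the deficient arrays by 3.74 ± 0.18 (13.4-fold; adjusted p = 2.10e-08), the guanylate-binding protein genes Gbp2b, Gbp5 and Gbp4 by 3.64 ± 0.24, 3.43 ± 0.21 and 3.17 ± 0.19, and Ido1 by 3.31 ± 0.16. The myeloid receptor gene Adgre4 was higher by 3.53 ± 0.10. Granzyme A, Gzma, was higher by 3.00 ± 0.11 and Jchain by 3.15 ± 0.16. Among genes that were lower, the potassium channel Kcnma1 led with -3.65 ± 0.38 (-1.80 as the mean of its probe sets), followed by the Wnt antagonist Frzb (-2.62 ± 0.11) and the hormone stanniocalcin, Stc1 (-2.34 ± 0.09). The imprinted genes Peg10 and Peg3 were lower by -2.30 ± 0.09 and -2.20 ± 0.10, and the matrix proteinases Mmp13 and Mmp3 by -2.28 ± 0.14 and -2.10 ± 0.12.

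All 33 mitotic genes were lower, over all genes and adjusted over the list alone, with a median of -1.13 (adjusted p = 3.82e-18; adjusted p = 0.139 with an estimated correlation). The centromere gene Cenpf was lower by -1.19 ± 0.11, cyclin B2, Ccnb2, by -1.36 ± 0.13 and Mki67 by -1.11 ± 0.14. DNA replication genes had 30 of 31 lower (31 adjusted over the list alone) with a median of -0.83, and ribosomal protein genes 21 of 25 lower (22 adjusted over the list alone) with a median of -0.33. Their adjusted p was 0.139 and 0.104 with an estimated correlation. Hypoxia and glycolysis genes had 15 of 26 lower and 5 higher (16 and 5 adjusted over the list alone) with a median of -0.38, an adjusted p of 0.518 with an estimated correlation, and no call with median centring (adjusted p = 0.0506) or without wild type air replicate 3 (adjusted p = 0.0539). The phosphofructokinase gene Pfkl was lower by -0.62 ± 0.09, and the regulatory enzyme Pfkfb3 was higher by 1.55 ± 0.07. Myc was lower by -0.72 ± 0.14, and Ccnd1 at -0.18 ± 0.09 did not pass (adjusted p = 0.166).

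Markers of lung cells moved against these genes. All 23 alveolar epithelial markers were higher (median 0.86) and all 23 endothelial markers were higher (median 0.95), both also adjusted over the list alone. The lymphatic and type I cell gene Pdpn was higher by 1.11 ± 0.07, surfactant protein D, Sftpd, by 1.36 ± 0.09 and Pecam1 by 1.24 ± 0.07. Sftpc was higher by 0.22 ± 0.06, a call lost with median centring (adjusted p = 0.125). Airway markers had 15 of 23 higher (17 higher and 1 lower adjusted over the list alone) with a median of 0.59, and Bpifa1, a secreted airway protein, was higher by 1.76 ± 0.11. The adjusted p with an estimated correlation was 0.0957, 0.0711 and 0.104 for the alveolar, endothelial and airway lists. Epithelial junction genes (14 of 19, median 0.57), smooth muscle markers (9 of 13, median 0.47; 10 adjusted over the list alone), cardiac and skeletal muscle markers (12 of 19, median 0.66) and adipocyte and mesothelial markers (9 of 13, median 0.70) were higher too. Unless given, the counts were the same adjusted over the list alone. These 4 lists had an adjusted p of 0.0957, 0.139, 0.116 and 0.122 with an estimated correlation. Cardiac Nppa was higher by 2.40 ± 0.10 and the adipocyte hormone Adipoq by 1.34 ± 0.07.

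Interferon response genes had 25 of 26 members higher (25 adjusted over the list alone) with a median of 1.25 (adjusted p = 5.47e-13; adjusted p = 0.152 with an estimated correlation). Gbp3 was higher by 3.12 ± 0.21, the RNA sensor Ifih1 by 1.5 ± 0.13 and the transcription factor Stat2 by 1.04 ± 0.10. MHC class II genes were higher in 10 of 10 (10 adjusted over the list alone) with a median of 1.82, and MHC class I presentation genes in 11 of 12 (11 adjusted over the list alone) with a median of 0.83. Ciita was higher by 1.78 ± 0.08, the class II loading gene H2-DMa by 1.94 ± 0.10 and the immunoproteasome gene Psmb9 by 2.09 ± 0.12. The adjusted p with an estimated correlation was 0.0711 and 0.1. Alveolar epithelial markers were higher by a median of 0.86 in the same comparison. The interferon genes had a mean of 8.18 in wild type air replicate 1, 7.38 and 7.39 in the other wild type air arrays, and 9.0 ± 0.04 in deficient air.

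Immune cell markers were higher. T and NK cell markers had 26 of 30 higher (27 adjusted over the list alone) with a median of 0.77, among them the cytotoxic granule gene Nkg7 at 2.32 ± 0.08 and the T cell receptor subunit Cd3g at 1.83 ± 0.08. B and plasma cell markers had 16 of 17 higher (16 adjusted over the list alone) with a median of 0.67, and macrophage and monocyte markers 21 of 25 (21 adjusted over the list alone) with a median of 0.67. Csf1r was higher by 1.23 ± 0.06. The adjusted p of these 3 lists was 0.0711, 0.0957 and 0.104 with an estimated correlation. Dendritic cell markers had 9 of 14 higher and 1 lower (11 and 1 adjusted over the list alone) with a median of 0.55, and an adjusted p of 0.0711 with an estimated correlation. Alveolar macrophage and smoke-macrophage markers had 13 of 16 higher (14 adjusted over the list alone) with a median of 0.94, among them Itgax, which encodes CD11c, at 1.58 ± 0.13. Neutrophil markers had 13 of 24 higher (14 adjusted over the list alone) with a median of 0.40, among them lipocalin 2, Lcn2, at 2.18 ± 0.12. The alveolar and smoke-macrophage call and the neutrophil call held with an estimated correlation (adjusted p = 0.0215 and 0.0283).

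NF-kB targets were higher in 19 of 36 and lower in 4 (21 and 4 adjusted over the list alone), with a median of 0.34 and an adjusted p of 0.146 with an estimated correlation. The ubiquitin-editing enzyme Tnfaip3 was higher by 0.90 ± 0.07, Icam1 by 1.11 ± 0.08, Il1b by 1.80 ± 0.24 and Tnf by 0.68 ± 0.08. Cytokine receptor and TNF pathway genes had 20 of 25 higher and 2 lower (22 and 2 adjusted over the list alone) with a median of 0.56, and Tnfrsf1b was higher by 1.68 ± 0.10. Immune checkpoint genes had 8 of 14 higher (8 higher and 1 lower adjusted over the list alone) with a median of 0.27, and Cd274 was higher by 2.44 ± 0.12. The adjusted p of these lists was 0.0711 and 0.1 with an estimated correlation. Immediate early genes had 13 of 18 higher and 1 lower (13 and 1 adjusted over the list alone) with a median of 0.47, among them the nuclear receptor Nr4a1 at 1.79 ± 0.07, and that call held with an estimated correlation (adjusted p = 0.0283). Macrophage markers were higher by a median of 0.67 beside these lists.

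Over all genes 7674 differed, 4083 higher and 3591 lower in the deficient arrays, and 670 were higher and 261 lower at least 2-fold. The groups did not overlap for 51.9% of genes (10% by chance). With median centring 39.6% of the genes that differed were higher in place of 53.2%. Of the lists 30 were called, 26 higher and 4 lower, and 3 held with an estimated correlation.

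**Figure D3:**
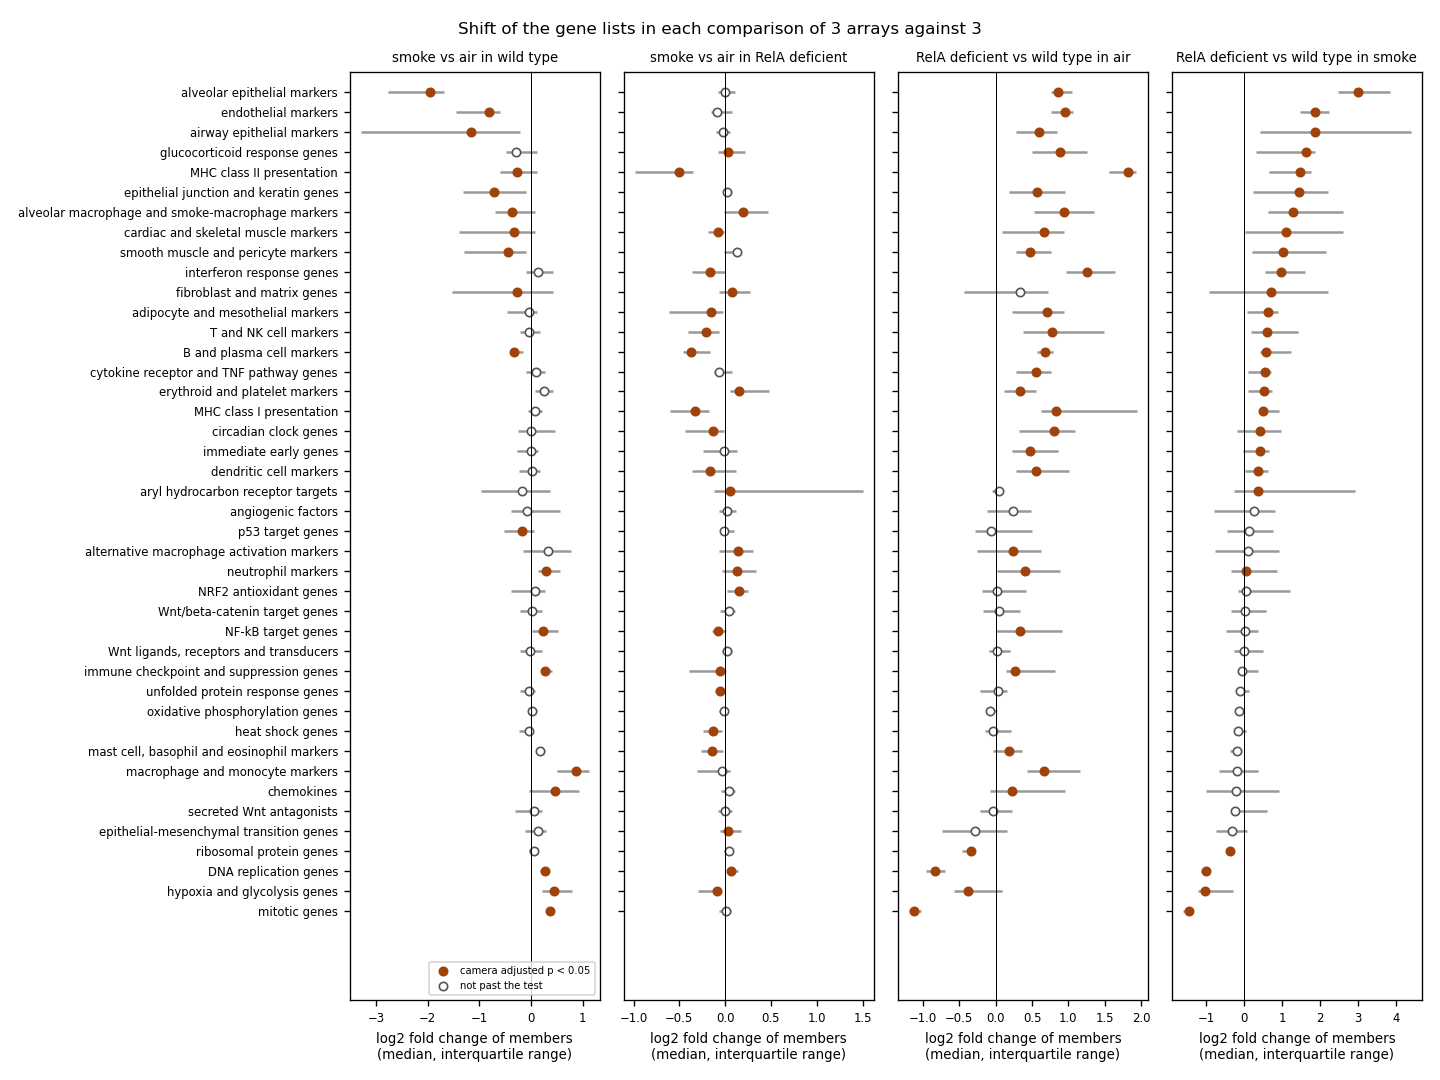
Median log2 fold change of the members of each of 42 gene lists (points, with the interquartile range as grey bars; horizontal axes in log2 units) in the 4 comparisons of 3 arrays against 3. Filled points passed camera's test with its preset correlation; alveolar markers lay at -1.96 for smoke in wild type and at 2.99 for genotype in smoke.

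Host genotype was then compared in smoke. Cyp2f2 was higher in the deficient arrays by 5.90 ± 0.08 (59.8-fold; adjusted p = 5.12e-14) and Cyp1a1 by 5.89 ± 0.10. They were followed by Ces1d at 5.59 ± 0.13, Reg3g, an antimicrobial lectin, at 5.33 ± 0.10, H2-Ea at 5.30 ± 0.32, Retnla at 5.15 ± 0.11 and Aldh1a1 at 5.09 ± 0.07. Among genes that were lower, Cd5l led with -2.92 ± 0.23 (adjusted p = 2.02e-07), followed by the hypoxia-inducible prolyl hydroxylase Egln3 (-2.72 ± 0.21), Lrrc15, a surface protein of matrix-forming fibroblasts (-2.71 ± 0.19), Adm (-2.61 ± 0.13), Arg1 (-2.39 ± 0.18) and Cxcl2 (-2.26 ± 0.21). Cyp1a1 (5.65 ± 0.13), Reg3g and Retnla in wild type smoke and Cd5l in deficient smoke lay below the level of the intensity filter. That level is a chosen setting and not a measured limit of detection. Their differences and interactions against those groups may be compressed in size, which was not tested.

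All 33 mitotic genes were lower (median -1.46) and all 31 DNA replication genes were lower (median -1.01), both also adjusted over the list alone. The adjusted p was 3.89e-13 and 2.53e-10, and 0.228 for both with an estimated correlation. Cenpf was lower by -1.76 ± 0.11, Mki67 by -1.48 ± 0.14, the licensing factor Cdt1 by -1.26 ± 0.11 and Myc by -1.60 ± 0.14. Hypoxia and glycolysis genes had 20 of 26 lower and 4 higher (the same adjusted over the list alone) with a median of -1.03 and an adjusted p of 0.299 with an estimated correlation. Ndrg1 was lower by -1.84 ± 0.11 and Vegfa higher by 1.88 ± 0.07. Ribosomal protein genes had 23 of 25 lower (23 adjusted over the list alone) with a median of -0.37 and an adjusted p of 0.228 with an estimated correlation.

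Lung markers were higher beside these falls. All 23 alveolar epithelial markers (median 2.99) and all 23 endothelial markers (median 1.86) were higher, and 18 of 23 airway markers (median 1.85), with the same counts adjusted over the list alone. The adjusted p was 0.0992 for each with an estimated correlation. Ager was higher by 3.73 ± 0.07, Sftpc by 1.75 ± 0.06, Tek by 3.78 ± 0.07 and Scgb3a1 by 4.65 ± 0.10. Fibroblast and matrix genes had 16 of 27 higher and 11 lower (the same adjusted over the list alone) with a median of 0.71 and an adjusted p of 0.142 with an estimated correlation. Alveolar macrophage and smoke-macrophage markers had 13 of 16 higher and 2 lower (the same adjusted over the list alone) with a median of 1.28, and this was the 1 call that held with an estimated correlation (adjusted p = 0.0239). Chil3 was higher by 3.93 ± 0.14.

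Interferon response genes had 23 of 26 higher (23 adjusted over the list alone) with a median of 0.97, MHC class II genes 9 of 10 (9 adjusted over the list alone) with a median of 1.46, and T and NK cell markers 22 of 30 higher and 1 lower (22 and 2 adjusted over the list alone) with a median of 0.61. The adjusted p of these lists was 0.299, 0.142 and 0.142 with an estimated correlation. Ifit3 was higher by 2.68 ± 0.17, Cd74 by 2.32 ± 0.11 and Cd3g by 2.44 ± 0.08. Macrophage and monocyte markers were not called, with 8 higher and 11 lower of 25 (the same adjusted over the list alone) and a median of -0.18. NF-kB targets were not called either, with 11 higher and 11 lower of 36 (the same adjusted over the list alone) and a median of 0.02. Chemokines had 13 higher and 15 lower of 32 (the same adjusted over the list alone) and no call. Aryl hydrocarbon receptor targets had 5 of 9 higher and 2 lower (the same adjusted over the list alone) with a median of 0.36 and an adjusted p of 0.142 with an estimated correlation. That median was 2.61 with the intensity filter and 0.22 with median centring.

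In this comparison 11886 genes differed, 4518 higher and 7368 lower, with 1478 higher and 510 lower at least 2-fold, and 61.3% of genes did not overlap between the groups (10% by chance). The median change of all genes was -0.14 and became -0.28 with median centring, which took the share of higher genes among those that differed from 38.0% to 22.9%. Ctnnb1, which encodes beta-catenin, was higher by 0.23 ± 0.06, a call lost with that centring (adjusted p = 0.193). Of the lists 26 were called, 22 higher and 4 lower.

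The interaction term asked whether the smoke effect differed between genotypes, as the change with smoke in the deficient arrays minus that in wild type. Cyp1a1 differed most, by 7.21 ± 0.14 (adjusted p = 6.24e-12): it rose by 5.08 in the deficient arrays and fell by 2.13 in wild type. H2-Ea, Cyp2f2, Ces1d, Scgb1a1 and Retnla differed by 5.87 ± 0.45, 5.22 ± 0.11, 4.66 ± 0.19, 4.53 ± 0.16 and 4.45 ± 0.16. On the negative side stood Cd5l (-3.60 ± 0.33), the membrane protein gene Ms4a4a (-2.47 ± 0.19), Igkv19-93 (-2.46 ± 0.15; -1.32 as the mean of its probe sets), Cxcl2 (-2.28 ± 0.29), the Fc receptor gene Fcgr4 (-2.26 ± 0.40) and Clec4e, which encodes Mincle (-2.22 ± 0.28).

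The alveolar list had 23 of 23 members with a positive interaction (median 2.10), the airway list 15 of 23 (median 1.11; 15 and 1 negative adjusted over the list alone) and the endothelial list 18 of 23 (median 0.84; 19 adjusted over the list alone). Aryl hydrocarbon receptor targets had 5 positive and 2 negative of 9 (median 1.47, and 2.23 with the intensity filter), alveolar macrophage and smoke-macrophage markers 9 and 3 of 16 (median 0.77; 9 and 4 adjusted over the list alone) and fibroblast genes 15 and 5 of 27 (median 0.37; 15 and 7 adjusted over the list alone). Where not given, counts were the same adjusted over the list alone. These 6 calls held with an estimated correlation, at an adjusted p of 0.0479 for the endothelial list and 0.0348 for the others. Tek differed by 2.66 ± 0.10, Sftpb by 2.79 ± 0.11, Cyp1b1 by 2.53 ± 0.15 and Car4 by 3.58 ± 0.16.

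Macrophage and monocyte markers had 17 negative and 2 positive of 25 (20 and 2 adjusted over the list alone) with a median of -0.97, hypoxia and glycolysis genes 17 and 2 of 26 (22 and 2 adjusted over the list alone) with -0.46, and NF-kB targets 17 and 3 of 36 (19 and 3 adjusted over the list alone) with -0.36. Their adjusted p was 0.208, 0.244 and 0.294 with an estimated correlation. Adgre1, which encodes F4/80, differed by -1.71 ± 0.17, Adm by -1.81 ± 0.18, Tnf by -0.84 ± 0.11 and Il1b by -1.38 ± 0.33. Mitotic genes had 3 negative of 33 (2 adjusted over the list alone) with a median of -0.38 and an adjusted p of 0.656 with an estimated correlation. Myc differed by -0.88 ± 0.19. Chemokines (median -0.44, and -0.26 without wild type air replicate 3; 12 negative and 4 positive of 32; 15 and 5 adjusted over the list alone) had an adjusted p of 0.0351, and of 0.485 with an estimated correlation. That call held in 11 of 19 settings and was lost with array weights (adjusted p = 0.113), with median centring (0.115), and without wild type air replicate 2 (0.0696), wild type smoke replicate 1 (0.140) or 2 (0.0545), deficient air replicate 2 (0.0505) or deficient smoke replicate 1 (0.0524) or 3 (0.0894). Alveolar markers differed by a median of 2.10 beside all of these.

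In all 2909 genes had an interaction, 1773 positive and 1136 negative, and 4969 did without wild type smoke replicate 1. With median centring 41.4% of them were positive in place of 60.9%. Of the lists 22 were called, 13 higher and 9 lower. The smoke changes in both genotypes correlated across the 19937 genes with r = 0.0943 and rho = 0.167, and genes are not independent replicates. Of the changed genes 34 rose and 139 fell with smoke in both genotypes, against 20.7 and 47.9 for independent sets (Fisher's exact p = 0.00263 and 2.72e-34). A further 49 rose in the deficient arrays and fell in wild type (19.3 for independent sets; Fisher's exact p = 1.63e-10), and 71 fell in the deficient arrays and rose in wild type (51.5; Fisher's exact p = 0.00462). Both comparisons used the same estimate of spread for a gene, which can raise all of these overlaps above the number for independent sets.

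Averaged over genotypes, 3789 genes differed between smoke and air, 1398 higher and 2391 lower, and 6394 without wild type smoke replicate 1. Esm1, an endothelial tip cell gene, rose by 1.28 ± 0.07, the lipase inhibitor Angptl4 by 1.05 ± 0.07 and S100a8 by 0.62 ± 0.06. The average also held genes that moved oppositely, such as Cyp1a1 at 1.47 ± 0.07. With median centring 70.1% of 6371 genes were higher in place of 36.9%. Of the lists 26 were called and none held with an estimated correlation. Averaged over exposures, 12177 genes differed between the deficient and wild type arrays, 4996 higher and 7181 lower, with 25.2% in place of 41.0% higher under median centring. Bpifa1 was higher in the deficient arrays by 3.39 ± 0.08 and Ly6i by 3.21 ± 0.13, and the matrix protein Thbs2 was lower by -2.27 ± 0.10, Islr by -2.26 ± 0.05 and Peg10 by -2.26 ± 0.06. Of 28 lists called, that of alveolar macrophage and smoke-macrophage markers held with an estimated correlation (adjusted p = 0.023).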

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

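The smoke response was asked about in both genotypes before the values were seen, while every test of a technical explanation and every exchange of labels in this part was chosen after the result was seen. The smoke effect differed between genotypes for 2909 genes and 22 gene lists. Cyp1a1 led with an interaction of 7.21, followed by H2-Ea (5.87), Cyp2f2 (5.22), Ces1d (4.66), Scgb1a1 (4.53) and Retnla (4.45). Negative interactions were largest for Cd5l (-3.60), Ms4a4a (-2.47), Igkv19-93 (-2.46), Cxcl2 (-2.28), Fcgr4 (-2.26) and Clec4e (-2.22). Among genes named beforehand the interaction was 2.53 for Cyp1b1, 1.53 for Sftpc, -0.88 for Myc, -0.84 for Tnf, -1.38 for Il1b, -1.94 for Arg1 and 0.37 for Axin2, the last lost without wild type air replicate 3 (adjusted p = 0.0947). Of 98 named genes past the test for smoke in wild type 84 had an interaction, and 70 of 89 named for smoke in the deficient arrays had one. The naming rule favours such genes, and over all genes the share was 14.6%.

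Lists with a positive median interaction were alveolar epithelial markers (2.10), aryl hydrocarbon receptor targets (1.47), airway markers (1.11), endothelial markers (0.84), epithelial junction genes (0.84), alveolar macrophage and smoke-macrophage markers (0.77), smooth muscle markers (0.56), fibroblast genes (0.37), glucocorticoid targets (0.36), cardiac and skeletal muscle markers (0.25), p53 targets (0.21), Wnt ligands and receptors (0.0725) and NRF2 genes (0.0693). Lists with a negative median were macrophage and monocyte markers (-0.97), hypoxia and glycolysis genes (-0.46), chemokines (-0.44), MHC class I genes (-0.41), mitotic genes (-0.38), NF-kB targets (-0.36), checkpoint genes (-0.36), mast cell, basophil and eosinophil markers (-0.29) and DNA replication genes (-0.18). The alveolar, airway, endothelial, fibroblast, alveolar and smoke-macrophage, and aryl hydrocarbon receptor calls held with an estimated correlation, and the other 16 did not. With the preset correlation the calls of DNA replication genes (12 of 19 settings; adjusted p = 0.176 with array weights and 0.224 without wild type air replicate 2), mast cell, basophil and eosinophil markers (12 of 19; 0.573 with the intensity filter) and chemokines (11 of 19; 0.115 with median centring and 0.140 without wild type smoke replicate 1) were lost in several settings. Those of Wnt ligands (15 of 19; 0.107 with array weights and 0.104 without wild type smoke replicate 1) and glucocorticoid targets (18 of 19; 0.0788 with the intensity filter) were lost in fewer. Some of these medians moved: Wnt ligands to 0.00599 and NRF2 genes to 0.00286 with median centring, muscle markers to 0.15 and NRF2 genes to 0.0178 without wild type smoke replicate 1 and 3, NRF2 genes to 0.0445 without deficient air replicate 3, DNA replication genes to -0.11 and -0.29 without wild type air replicate 2 and deficient smoke replicate 1, and chemokines to -0.26 without wild type air replicate 3.

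Mitotic genes were lower and alveolar markers higher in the deficient arrays. A different share of lung beside tumour tissue could give both, and within groups the mitotic mean fell as the alveolar mean rose, with r = -0.417 over 12 arrays (exact permutation p = 0.198; r = -0.552 without the 2 farthest arrays), which cannot tell. With smoke in wild type 6 bright airway genes fell further than 15 bright alveolar genes, by -1.47 (permutation p = 0.00605; -1.44 for 9 and 22 genes with no upper limit of brightness). Over all 23 airway and 23 alveolar genes the difference was 0.80, in the opposite direction (permutation p = 0.0954). Of the airway genes 14 were dimmer, where a fall can be compressed. The permutation also treats genes of the same arrays as independent. It therefore cannot tell 1 share that scales all lung cells alike from a share that differs between cell types, and both stay open. For the interferon and MHC class II genes in air, 36 genes were set against 28 bright alveolar, airway, and cardiac and skeletal muscle genes. The median of the 36 exceeded that of the 28 by 0.52 (permutation p = 4.40e-04). The highest of the 28 rose by 2.40, the rise given above for the cardiac gene Nppa, and 2 of the 36 lay above it. A muscle gene need not follow the share of alveolar or airway tissue, so this bound cannot decide. A larger share stays open too. An effect of genotype on tumour growth or on immune cells stays open and untested. A count of tumour and lung cells in sections would measure the share of lung tissue, but not why it differed.

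Cyp1a1 rose with smoke in the deficient arrays and fell in wild type. The wild type change expected under dilution was the rise of the deficient arrays plus the largest fall of a bright lung list. By that sum wild type Cyp1a1 would still have risen by 1.68. It lay -3.81 (SE 0.14) from that value, or -1.86 with the fall of Cyp2f2. That gap rests on the Cyp1a1 levels in air, 7.79 in wild type and 6.47 in the deficient arrays. It argues only against an equal rise from each air level. Within smoke, Cyp1a1 and Cyp2f2 were higher in the deficient arrays by nearly the same amount, as given above. An equal level in smoke hidden by dilution therefore stays open, as does a smaller rise. For Cyp1b1, Nqo1 and Aldh3a1 the median gap was 0.93 (0.86 to 1.93), which cannot tell. Exchanged exposure labels in wild type would turn the fall of Cyp1a1 into a rise of 2.13 and that of Aldh3a1 into 0.97, with 0.18 for Cyp1b1 and -0.0319 for Nqo1 (median of the 4 genes 0.58). Over all changed genes 34 rose and 139 fell in both genotypes as labelled and 49 and 71 moved oppositely, each above the number for independent sets. The shared estimate of spread can raise all of these overlaps, so they cannot judge an exchange of labels, which stays open. A different time between the last exposure and tissue collection, or a host effect on the smoke response, stays open and untested, since the labels give no times.

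Exchanging group labels between arrays asked how often a grouping by chance gives as many calls, counting the real one. For the 4 comparisons of 3 arrays with 3 there are 10 splits, too few to judge, and 1 of 10, the real one, reached each real count. The real and highest other counts were 5778 and 2309 genes for smoke in wild type, 481 and 0 for smoke in the deficient arrays, 7674 and 0 for genotype in air, and 11886 and 0 for genotype in smoke. For lists they were 19 and 18, 25 and 18, 30 and 29, and 26 and 24. The 2309 genes came from the split of wild type air 1 and 3 and smoke 1 against air 2 and smoke 2 and 3. Array medians were 6.78 to 6.83 in the first set and 6.85 to 6.88 in the second. A difference between arrays that cuts across exposure therefore also gave many calls, and its cause was not tested. For the interaction and both averages 100 of 200 possible splits were drawn at random. For the interaction 2 of 100 splits reached 2909 genes (highest other 3728) and 11 of 100 reached 22 lists (highest other 28). Exchanging exposure in 1 genotype, which turns the interaction into the average, was not among the 100 and gives 3789 genes and 26 lists. For averaged smoke 1 of 100 reached 3789 genes (highest other 3728) and 3 of 100 reached 26 lists (highest other 28). For averaged genotype 1 of 100 reached 12177 genes (highest other 7068) and 8 of 100 reached 28 lists (highest other 29), so chance was not excluded for the list counts of the interaction and of averaged genotype. The splits also put real differences between groups into the spread within groups, which can lower their counts. An exchanged split of 3 arrays against 3 also keeps part of the real difference, which can raise the number of lists. For genotype in air the other splits called 0 genes but 22 to 29 lists. The splits therefore cannot judge chance for list counts in either direction, and they cannot exclude it for gene counts.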

How the results depend on the processing

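Settings were fixed before the values were seen, and no named gene reversed in those run for named genes (the 6 arrays alone gave counts only, and the intensity filter removed 7 of 332 named genes). Over all contrasts 277 of 294 list shifts kept their label with the intensity filter, 282 with array weights and 277 with median centring. In each contrast median centring moved the median change of all genes further from 0. It went from -0.03 to -0.11 for genotype in air and from -0.08 to -0.14 for the interaction. Calls lost or gained with that centring can follow from this offset. Leaving out 1 array kept 3412 of 3528 list shifts and 10214 of 10452 changes of named genes. Smoke in wild type gave 10211 genes with array weights, 9852 with median centring, 3454 with the 6 arrays alone, and 3695 to 8824 with 1 array left out. Smoke in the deficient arrays gave 1368 with array weights, 1018 with the 6 arrays alone and 261 to 717 with 1 array left out. The interaction gave 6662 with array weights and 2239 to 4969 with 1 array left out, and averaged smoke 8473 with array weights, 6371 with median centring and 2858 to 6394. The cause was not tested. With an estimated correlation the lists called were 0 and 5 for smoke in wild type and deficient arrays, 3 and 1 for genotype in air and smoke, 6 for the interaction, 0 for averaged smoke and 1 for averaged genotype, and fry called 29 for smoke in wild type. With 1 array left out the interferon shift with smoke in wild type ranged from -0.0664 to 0.38, and in the deficient arrays the mitotic shift from -0.17 to 0.11 and that of DNA replication genes from -0.0383 to 0.15. The mast cell, basophil and eosinophil interaction went from -0.29 to 1.37e-04 with the intensity filter.

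With the replicate number as a replicate block the gene counts were 6084, 440, 7778, 11919, 3020, 4051 and 12229, and the list counts 19, 27, 30, 25, 22, 25 and 28, in the order smoke in wild type, smoke in deficient arrays, genotype in air, genotype in smoke, interaction, averaged smoke and averaged genotype. The labels give no pairing, and the deviations of arrays that share a number correlated with r from -0.36 to 0.37. The every probe set setting was not run for lists.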

Other observations

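These values were singled out after they were seen, and none has a test of its own beyond the limma comparison named. Clock output genes were higher in the deficient arrays in air: Dbp, a transcription factor of the circadian output, lay at 8.12 ± 0.14 in wild type air, 7.92 ± 0.08 in wild type smoke, 10.03 ± 0.12 in deficient air and 9.02 ± 0.06 in deficient smoke (n = 3 arrays per group). The repressor gene Nr1d1 was higher in air by 1.68 ± 0.08, and Per3 by 1.13 ± 0.07. The clock gene Arntl went the other way, at 8.23 ± 0.06 in wild type air and 7.53 ± 0.05 in deficient air. Of 16 circadian genes 12 were higher and 1 lower (12 and 2 adjusted over the list alone), with a median of 0.80 and an adjusted p of 0.0711 with an estimated correlation. With smoke in the deficient arrays 5 of 16 fell (7 adjusted over the list alone), among them Nr1d1 by 0.95 ± 0.08 and Dbp by 1.01 ± 0.08, and the adjusted p was 0.0716 with an estimated correlation. Glucocorticoid targets had 11 of 12 higher and 1 lower in air (the same adjusted over the list alone), among them the zinc finger gene Zbtb16 at 2.71 ± 0.09 and Tsc22d3 at 1.25 ± 0.07, with an adjusted p of 0.0711 with an estimated correlation. Lung markers were higher in the same comparison, by medians of 0.86 (alveolar), 0.95 (endothelial) and 0.59 (airway), close to the 0.80 of the circadian and 0.88 of the glucocorticoid list. Arntl moved against all of these. The labels give no time of tissue collection, and the cause of these shifts was not tested.

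H2-Ea, an MHC class II chain gene, lay at 9.71 ± 0.24 in wild type air, 6.22 ± 0.64 in wild type smoke, 9.14 ± 0.71 in deficient air and 11.5 ± 0.03 in deficient smoke, while the 10 MHC class II genes listed beforehand, without H2-Ea, shifted with smoke in the deficient arrays by a median of -0.50. Trim12a, a tripartite motif gene, fell with smoke in the deficient arrays by 2.73 ± 0.10 and Trim30d by 1.74 ± 0.10. Trim30d reached 5.68 ± 0.15 in deficient smoke, below the level of the intensity filter, so its fall may be compressed.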
